A study of Mus musculus with 2 samples.

How the data were processed

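RNA from the cranial sutures (coronal, sagittal and lambdoid) of wildtype mouse pups at postnatal day 3 was profiled in 2 libraries, called library 1 and library 2 here after the replicate number in their titles. Both carry the same batch number, and together they form 1 group. The labels give suture stem cells as the cell type, whereas the extraction protocol describes whole suture tissue and no sort, so the libraries were treated as bulk tissue. Per the labels' protocols, total RNA was extracted with a column kit and libraries were built with the Ion AmpliSeq mouse transcriptome panel, which amplifies a short stretch of each gene with gene-specific primers. Read numbers from such a panel do not grow with gene length, but each amplicon has its own efficiency, so the order of different genes within a library is less certain than the difference of 1 gene between libraries. The genome build mm10 is named in the submitters' processing notes. The aligner, the counting tool and the filters are not given in the sources used here.

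The authors deposited CPM values, the reads of a target scaled to the total of its library, for 23930 amplicon targets, 1 per gene symbol, with a column per library. CPM had been computed by the authors within each library, and no scaling between libraries other than to the library total was visible in the values. Every value above 0 was a whole multiple of 1 step per library, within 0.01 of a read, for 100% of values in both libraries, and the largest departure was 0.00791 of a read. The step was 0.177 CPM in library 1 and 0.0633 CPM in library 2, so the reads behind each value could be recovered. They summed to 5663344 reads in library 1 and 15802610 in library 2. The limit that a count of 0 allows, 3 reads, corresponds to 0.530 CPM in library 1 and 0.190 CPM in library 2. The panel reads carry no molecular identifiers, so intervals and limits cover counting error only. A date stood in place of 27 gene symbols, and these were restored from the target names. Of the targets, 21370 (89.3%) had a symbol in GENCODE M21, whose GRCm38 coordinates are those of mm10. Cnmd was read under its older symbol Lect1.

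Levels were taken as CPM with the SD over the 2 libraries, with exact 95% Poisson intervals of the recovered reads, and as log2(CPM + 1) with a pseudocount of 1 CPM. This scale understates the change of genes near 1 CPM. A gene was called detected at 1 CPM or more in both libraries, and a second level of 10 CPM was used for well-measured genes. A total of 45 gene lists holding 499 genes was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. For 33 of those genes no target with that symbol was used here, among them Prrx1, Bglap, Gapdh and the adult globins. Each list's median was placed among the medians of 10000 random lists of the same size, drawn from all targets for levels and from 20 bins of mean CPM for differences between the libraries (members at a mean of 1 CPM or more). These percentiles describe the 2 libraries and are not p-values.

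The libraries were compared gene by gene with an exact two-sided binomial test on recovered reads, adjusted by Benjamini and Hochberg over 23930 targets at a threshold of 0.05. Pairs of genes within a library were compared with the same exact test against equal read numbers, as a family of 26 tests. These tests compare 2 libraries, or 2 amplicons in a library, and not conditions. The labels do not say whether the libraries came from separate pups or pools, so their spread may be partly technical. With 1 group of 2 libraries, no test between conditions could be made. On simulated reads for the 23930 targets with the depths of library 1 and library 2, the binomial test called 99% of 100 genes changed 2-fold, 69% of 100 genes changed 1.5-fold and 0.0169% of unchanged genes. Those reads held counting error only, whereas the libraries varied far more (chi-square 77.7 per degree of freedom), so these rates do not cover variation between samples. In a simulation on 14097 targets, 7% of 200 random lists of 10 genes fell outside the central 95% of matched random lists, and 95.5% of lists shifted by 1 on the log2 scale lay above the 97.5th percentile. There the differences were shuffled over genes, so members of a list did not vary together as markers of 1 cell type may.

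Named genes were all members of the Hedgehog and Cxcl12 lists, the 3 highest members of every other list, the lowest member of the suture, osteoblast and craniosynostosis lists, the 10 highest genes of all, and the 10 most raised genes in each library at a mean of 10 CPM or more. Some genes that the rule takes are not reported here by name, though counts and medians of their lists include them. Genes named beyond this rule were chosen after their values were seen. In the report these are Six2, Msx1, Axin2, Ctsk, Lepr, Cx3cl1, Il6, Il1b, Myh11, Rplp0, Rps15, Malat1, Xist, Ryr1 and Neb. In the closing section they are Omp, Cnga2, Gnal, Foxj1, Amelx, Ambn, Folr1, Clic6 and Kdm5d. Alternatives were other pseudocounts, detection levels and expression filters, rescaling of the libraries, removal of the 20 most abundant genes, and leaving out each library. Thinning library 2 to the reads of library 1, dropping the pseudocount and applying the exact binomial test to the count of differing genes were added after the data had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.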

Results

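Gene expression was measured in 2 bulk RNA libraries of cranial suture tissue from wildtype mouse pups at postnatal day 3. The cranial sutures are the fibrous joints between the skull bones, where bone grows and where suture stem cells reside. The series title names Cxcl12 and the Hedgehog ligands Shh and Ihh as niche factors, so the libraries show which of these signals, their receptors and the neighbouring cell types were present in the newborn tissue. Library 1 held 5663344 reads and library 2 held 15802610. Of 23930 amplicon targets, 13157 (55.0%) reached 1 CPM in both libraries and 8278 reached 10 CPM in both. Across all targets the libraries had a Pearson r of 0.962 and a Spearman rho of 0.944 on log2(CPM + 1). These are correlations across genes, which are not independent replicates. The most abundant target was a bone matrix gene. Col1a1, the main collagen chain of bone, took 11.9% of the reads of library 1 and 13.3% of library 2. By mean CPM the other members of the 10 highest genes were Rpph1, Col1a2, Rmrp, Sparc, Mylpf, Actb, Acta1, H19 and Acta2, in this order. Rpph1 and Rmrp are RNA component genes.

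The first question was which Hedgehog ligands the tissue expressed. Ihh, a ligand known from growth cartilage and bone, was the highest of the ligands at 7.76 CPM ± 5.23 (SD, n = 2). Dhh, a ligand known from Schwann cells, stood at 5.49 CPM ± 4.77 (SD, n = 2). Shh was the lowest at 0.911 CPM ± 1.04 (SD, n = 2) and reached 1 CPM in library 2 only. It was read 1 time in library 1 and 26 times in library 2. Ihh reads outnumbered Shh reads 22.9 to 1 in library 1, with an exact 95% interval from 3.73 to 947. In library 2 the ratio was 6.96, with an interval from 4.60 to 10.9. The exact two-sided binomial test against equal reads gave adjusted p = 4.56e-06 in library 1 and 3.24e-29 in library 2. Ihh and Dhh were closer, at a ratio of 1.92 (interval 0.915 to 4.23, adjusted p = 0.101 in the exact test) in library 1. In library 2 that ratio was 1.29 (interval 1.03 to 1.62, adjusted p = 0.0348 in the exact test). Such intervals and tests cover counting error of the reads and not the efficiency of each amplicon, so they do not order the expression of the genes. All 3 ligands were higher in library 2 in the exact test, both over all targets and adjusted over the list alone, where 3 of 3 were called. Over the 2 ligands at a mean of 1 CPM or more, the median difference of -1.48 on the log2 scale lay at percentile 5.11 of matched random lists, inside their central 95%. The adjusted p over all targets was 0.0170 for Shh, 1.03e-06 for Ihh and 9.34e-08 for Dhh. In the annotation, Shh lies on mm10 chromosome 5 from 28456815 to 28467256, Ihh on chromosome 1 from 74945315 to 74951672 and Dhh on chromosome 15 from 98891152 to 98898540. The position of the amplicons within these genes is not given in the sources used here. As a background, intronless genes of receptor and keratin-associated families averaged 0.330 CPM per target in library 1 and 0.237 CPM in library 2, and families with several coding exons averaged 0.0297 and 0.0395 CPM. Shh, which has several coding exons, lay between these averages in library 1, at 0.177 CPM from 1 read, and above both in library 2, at 1.65 CPM. Library 2 also held more reads of olfactory and tooth germ genes (closing section), so its Shh reads need not come from suture cells.

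The receiving side of the pathway was expressed far above the ligands. All 12 genes of Hedgehog reception and response reached 1 CPM in both libraries and 10 reached 10 CPM. Their median level lay at the 99.96th percentile of random lists, against percentile 54.3 for the ligands. Random lists include silent targets, so lists of expressed genes rank high. Among genes at a mean of 1 CPM or more only, the percentiles were 98.3 and 13.7, the latter without Shh. Smo, the signal transducer of the pathway, stood at 169 CPM ± 52.3 (SD, n = 2) and Ptch1, the ligand receptor and itself a Hedgehog target, at 93.4 CPM ± 39.5 (SD, n = 2). The co-receptor genes Cdon, Boc and Gas1 averaged 91.6, 70.9 and 66.8 CPM. Among the Gli transcription factors, Gli3 averaged 62.7 CPM, Gli1, a pathway target and suture stem cell marker, 48.2 CPM ± 23.0 (SD, n = 2), and Gli2 25.0 CPM. Sufu averaged 32.0 CPM, Hhip 17.9 and Disp1 5.10 CPM. In the exact binomial test between the libraries, 6 of the 12 genes were higher in library 2, 1 was higher in library 1 and 5 were not called, with the same counts adjusted over the list alone. For comparison, the test over all targets called 6351 of the 9192 genes at a mean of 10 CPM or more. Gli1 was 2.02-fold and Ptch1 1.85-fold higher in library 2 (adjusted p = 1.29e-19 and 1.20e-29, exact binomial test). Smo, Gli2 and Boc were also higher in library 2, and Gas1 was the gene higher in library 1. The median difference of the list, -0.47 on the log2 scale, lay at the 3.17th percentile of matched random lists, inside their central 95%.

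**Figure D1:**
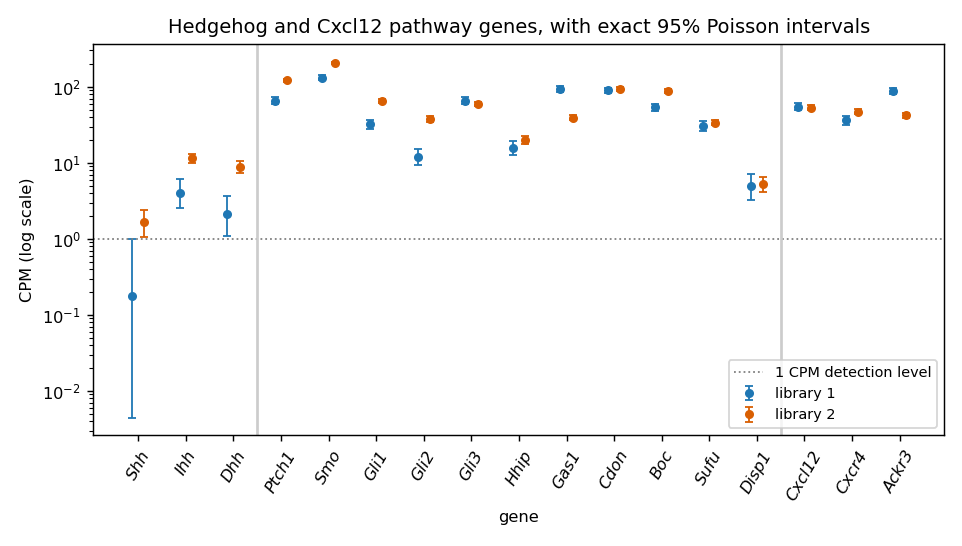
CPM (log axis) of the Hedgehog ligands, the named Hedgehog reception and response genes and Cxcl12 with its receptors, separated by grey lines; points are the 2 libraries and bars are exact 95% Poisson intervals of their recovered reads. The 3 ligands lie at or below 11.5 CPM, while Smo reaches 206 CPM, and Cxcl12 is at 54.9 and 53.3 CPM in library 1 and library 2.

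Cxcl12, a chemokine that retains and attracts stem and progenitor cells, was the other factor in question. It was expressed at 54.1 CPM ± 1.15 (SD, n = 2), and its reads did not differ detectably between the libraries (fold 1.03, adjusted p = 1 in the exact binomial test). The gene lies on mm10 chromosome 6 from 117168535 to 117181367. Of 35 chemokine ligands measured, 17 reached 1 CPM in both libraries (11 reached 2 CPM) and 6 reached 10 CPM. Cxcl12 ranked 3 in library 1 and 1 in library 2. The other leading ligands were Pf4, a platelet chemokine, at 114 and 51.1 CPM, and Ccl9 at 62.9 and 35.9 CPM. The place of Cxcl12 behind Ccl9 in library 1 was not resolved (ratio 0.874, interval 0.748 to 1.02, adjusted p = 0.101 in the exact test). In library 1 the ratio of Cxcl12 to Pf4 was 0.481 (interval 0.419 to 0.552) and in library 2 it was 1.04 (interval 0.946 to 1.15). Pf4 reads thus outnumbered Cxcl12 reads in library 1, and the order of the pair was not resolved in library 2 (adjusted p = 0.402, exact test). Amplicon efficiency is not covered by these tests, so they compare reads and not the expression of the genes. Cx3cl1, a membrane-bound chemokine, was at 34.4 and 48.1 CPM. The lead of Cxcl12 over it in library 2 was not resolved either (ratio 1.11, adjusted p = 0.0532 in the exact test). Both Cxcl12 receptors were expressed. Cxcr4, the signalling receptor, stood at 41.6 CPM ± 7.70 (SD, n = 2) and Ackr3, the scavenging receptor, at 64.8 CPM ± 32.3 (SD, n = 2). They were the 2 highest of 21 chemokine receptors in each library, in opposite order, and Ccr1 followed at 20.7 CPM. Ackr3 was 2.09-fold higher in library 1 (adjusted p = 6.15e-32) and Cxcr4 1.30-fold higher in library 2 (adjusted p = 0.00275), both in the exact binomial test. Over all chemokine ligands, 10 were higher in library 1, 3 were higher in library 2 and 22 were not called, with the same counts adjusted over the list alone. The median difference was 0.67 on the log2 scale for chemokine ligands and 0.58 for chemokine receptors, at percentiles 99.98 and 98.5 of matched random lists and thus outside their central 95% toward library 1. For the receptors this did not hold with a pseudocount of 5 CPM or for members at a mean of 10 CPM or more.

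Across the 17 signalling lists, 162 memberships reached 1 CPM in both libraries. All 14 Wnt receptors and co-receptors were detected, led by Lrp5 (215 CPM), Lrp6 (116 CPM) and Ryk (93.3 CPM), against 10 of 19 Wnt ligands, led by Wnt5b (36.9 CPM), Wnt5a (22.4 CPM) and Wnt4 (22.1 CPM). All 13 secreted Wnt antagonists were detected, with Wif1 at 269 CPM and Sfrp2 at 227 CPM, followed by Dkk3 at 71.2 CPM. All 5 FGF receptors were detected, with Fgfr1 at 494 CPM, Fgfr2 at 188 CPM and Fgfr3 at 90.1 CPM. Of the FGF ligand list 12 of 21 genes were detected, and none exceeded an average of 21.8 CPM (Fgf1). Fgf11 and Fgf13 were the next highest members of that list at 14.9 and 12.7 CPM, though they code for intracellular family members rather than secreted ligands. BMP and GDF ligands were detected in 13 of 20 cases, led by Bmp1 (550 CPM), which codes for a procollagen protease rather than a growth factor, Gdf10 (80.9 CPM) and Bmp7 (60.5 CPM). BMP and activin receptors were detected in 8 of 9 cases, led by Bmpr2 (145 CPM), Acvr1 (77.4 CPM) and Acvr2a (70.7 CPM). BMP antagonists were detected in 10 of 12 cases, with Fstl1 at 1229 CPM, Nbl1 at 101 CPM and Twsg1 at 63.1 CPM. All 7 TGF-beta genes were detected, with Tgfb1 at 516 CPM, Eng at 218 CPM and Tgfb3 at 186 CPM. Among 16 IGF, PDGF and VEGF genes, all detected, Igf2 stood at 1791 CPM, Igf2r at 368 CPM and Pdgfrb at 207 CPM. Notch genes were detected in 8 of 9 cases, with Notch2 at 262 CPM, Notch3 at 134 CPM and Jag1 at 74.7 CPM. Of 13 inflammatory cytokine genes, 4 reached 1 CPM in both libraries (7 in either library), and the highest were Il18 (12.1 CPM), Il33 (9.50 CPM) and Lif (7.87 CPM), while Il1b averaged 0.909 CPM and Il6 0.158 CPM.

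Markers of suture mesenchyme and bone were compared with genes of tissues that had not been sampled. Among 18 genes of testis, retina, pancreas, liver and kidney, 2 reached 1 CPM in both libraries, and their median lay at percentile 0.610 of random lists (1.62 without library 1 and 2.75 without library 2). In the exact binomial test 3 of the 18 were higher in library 1 and none in library 2, with the same counts adjusted over the list alone. Over the 4 compared, the median difference of 1.36 lay at percentile 99.97 of matched random lists. The highest were Apoa2 (3.31 CPM), Alb (3.07 CPM) and Prm2 (1.40 CPM). Of 20 suture mesenchyme and stem cell markers, 19 reached 1 CPM in both libraries and 16 reached 10 CPM. The list's median CPM was 46.7. Acta2 was by far the highest at 4913 CPM ± 3329 (SD, n = 2), followed by Eng and by Thy1 at 162 CPM. Acta2 codes for a protein near-identical to the actins of striated muscle. Whether its amplicon also reads their genes was not tested, so its value is uncertain. Its difference between the libraries was 1.51 on the log2 scale, beside medians of 1.59 for skeletal muscle markers and -0.28 for pericyte and smooth muscle markers. Acta2 outnumbered the smooth muscle myosin Myh11 329 to 1 in library 1 and 116 to 1 in library 2. Axin2 and Six2, markers used for suture stem and progenitor cells, averaged 46.6 and 46.8 CPM, and Ctsk and Lepr 33.0 and 28.8 CPM. Pthlh was the lowest at 0.215 CPM. In the exact binomial test, 5 suture markers were higher in library 1, 9 were higher in library 2 and 6 were not called, with the same counts adjusted over the list alone. Six2 differed from 18.2 CPM in library 1 to 75.5 CPM in library 2 (adjusted p = 4.46e-62) and Msx1 from 2.12 to 21.2 CPM (adjusted p = 8.28e-29), both in the exact binomial test. In the same test all 12 chondrocyte markers were higher in library 2 (median difference -1.30 on the log2 scale). So were all 6 tooth germ genes (-1.53) and 10 of 12 olfactory sensory neuron genes (-2.62), in lists written after the first values were seen. All 17 craniosynostosis genes were detected, from Cdc45 at 8.78 CPM to Fgfr1, with Runx2 at 189 CPM and Fgfr2 next. In the exact binomial test 3 of them were higher in library 1, 10 were higher in library 2 and 4 were not called, with the same counts adjusted over the list alone. Among all 9192 genes at a mean of 10 CPM or more the test called 6351. The number of calls therefore does not set the suture or craniosynostosis list apart from other expressed genes.

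All 10 osteoblast markers measured exceeded 10 CPM in both libraries, with a median of 521 CPM. Col1a1 stood at 126033 CPM, Col1a2 at 25113 CPM and the matrix protein gene Sparc at 14088 CPM, and Sp7, the transcription factor of committed osteoblasts, was lowest at 40.5 CPM. In the exact binomial test 8 of them were higher in library 2 and 2, Col1a2 and Sparc, were higher in library 1, with the same counts adjusted over the list alone. Osteocyte markers were led by Dmp1 (509 CPM), Phex (125 CPM) and Ackr3, which is also a Cxcl12 receptor. Osteoclast markers, all 10 detected, were led by Mmp9 (1569 CPM), Acp5 (961 CPM) and Nfatc1 (253 CPM). All 12 chondrocyte markers were detected, with Col2a1 at 1243 CPM ± 1181 (SD, n = 2), Col11a2 at 747 CPM and Acan at 592 CPM.

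**Figure D2:**
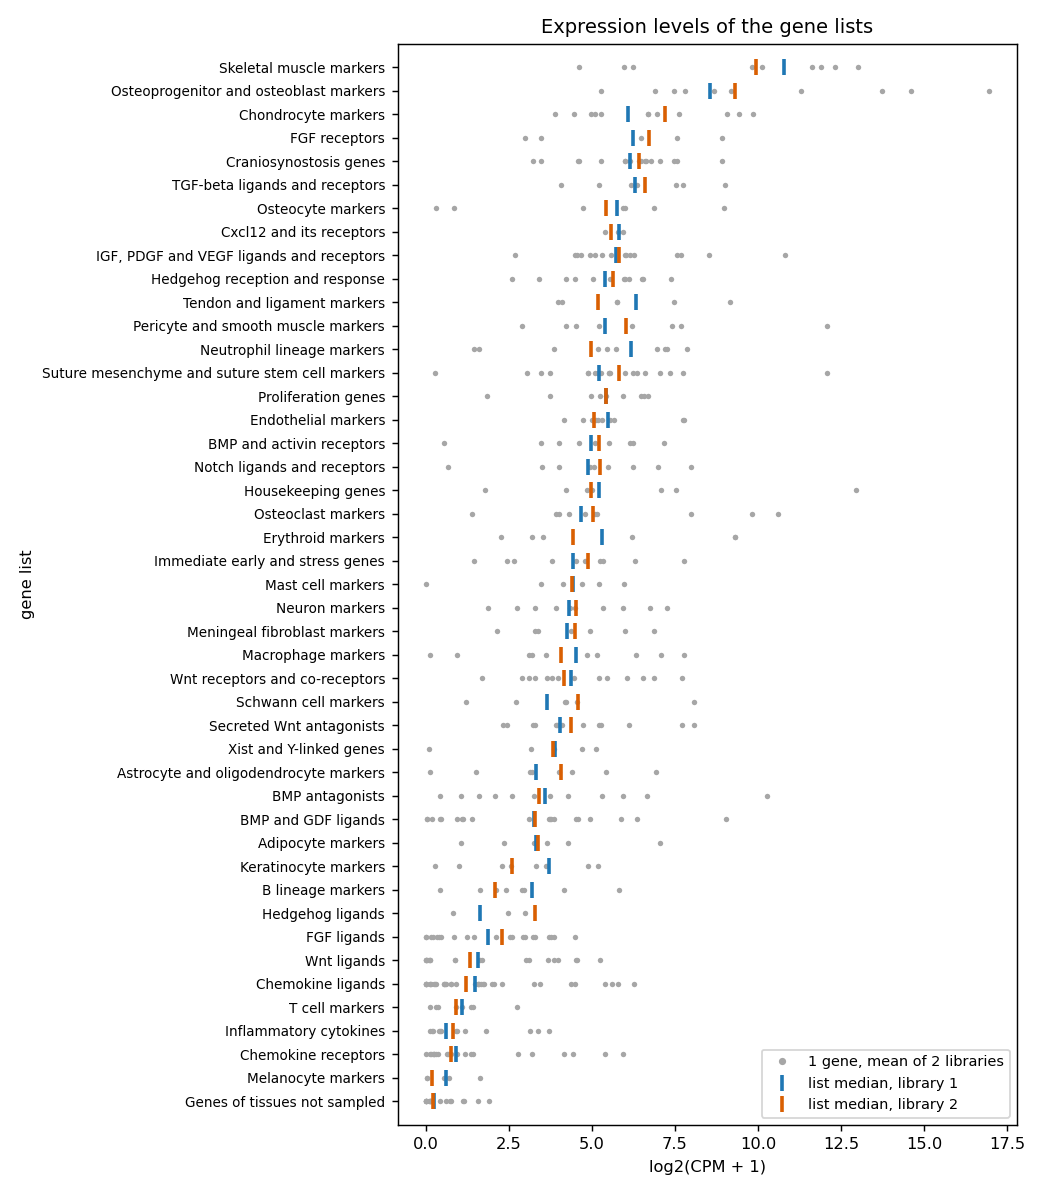
Expression level, log2(CPM + 1), of the members of the 45 gene lists (grey points, mean of the 2 libraries), with the list median in library 1 (blue) and library 2 (orange). Skeletal muscle and osteoblast markers have the highest medians, 10.1 and 8.93 as the median of member means, and genes of tissues not sampled have the lowest, 0.14.

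The libraries held markers of many further cell types, given here as means of the 2 libraries. Several of these lists differed between the libraries, as described below. Library 2 also held more reads of olfactory and tooth germ genes (closing section), so the markers need not all come from suture tissue. Skeletal muscle markers had the highest median of all lists, at 1126 CPM, with Mylpf at 9261 CPM, Acta1 at 6346 CPM and Myh8 at 4388 CPM. All 10 endothelial markers were detected, led by Pecam1 (224 CPM), Cdh5 (213 CPM) and Vwf (51.7 CPM). Pericyte and smooth muscle markers, all 8 detected, were led by Acta2, whose value is uncertain, Pdgfrb and Cspg4 (177 CPM). Tendon markers, all 6 detected, were led by Fmod (585 CPM), Tnmd (224 CPM) and Thbs4 (58.9 CPM). Blood lineages were present, with Alas2 at 639 CPM and Slc4a1 at 634 CPM for erythroid cells. Neutrophil markers were led by Ngp (277 CPM), Ltf (167 CPM) and S100a9 (157 CPM) and macrophage markers by Lyz2 (232 CPM), Cd68 (135 CPM) and Csf1r (80.9 CPM). B lineage markers were led by Ebf1 (56.1 CPM), Cd79b (19.0 CPM) and Pax5 (6.93 CPM) and mast cell markers by Tpsb2 (63.6 CPM), Cma1 (38.5 CPM) and Mcpt4 (25.3 CPM). T cell markers were low, with 4 of 8 detected and Cd4 highest at 5.85 CPM, ahead of Lck at 1.75 and Cd2 at 1.59 CPM. Neuron markers were led by Tubb3 (202 CPM), Stmn2 (120 CPM) and Nefl (74.8 CPM) and glial markers by Mbp (141 CPM), Slc1a3 (42.0 CPM) and Fabp7 (20.3 CPM). Schwann cell markers included Sox10 (27.8 CPM), and meningeal markers were led by Ptgds (133 CPM), Zic1 (69.7 CPM) and Foxc1 (30.1 CPM). Keratinocyte markers were led by Krt15 (35.3 CPM), Krt5 (30.6 CPM) and Krt14 (13.9 CPM) and adipocyte markers by Fabp4 (135 CPM), Cidec (18.6 CPM) and Pparg (11.5 CPM). Of 5 melanocyte markers 1, Pmel, was detected at 2.12 CPM, while Tyrp1 and Dct averaged 0.613 and 0.505 CPM. All 9 proliferation genes were detected, led by Ccna2 (105 CPM), Mcm2 (96.0 CPM) and Birc5 (90.8 CPM), and all 10 immediate early genes, led by Egr1 (228 CPM), Jun (77.7 CPM) and Fos (38.9 CPM). Housekeeping genes were led by Actb (7858 CPM), Sdha (199 CPM) and B2m (137 CPM). Levels of different genes rest on different amplicons. The ribosomal protein gene Rplp0 gave 2.41 CPM and Rps15 2126 CPM, although both code for subunits of the ribosome. Both libraries held reads of Y-linked genes, with Ddx3y at 34.6 CPM, Uty at 25.0 CPM and Eif2s3y at 13.6 CPM. Xist, expressed from the inactive X chromosome of females, had 0 reads in library 1, which allows up to 0.530 CPM, and 2 reads in library 2.

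The spread between the libraries was then examined. Skeletal muscle, tendon and neutrophil lists lay toward library 1, and chondrocyte, osteoblast, meningeal, neuron and Schwann cell lists toward library 2. Of 9192 genes at a mean of 10 CPM or more, 668 were at least 2-fold higher in library 1 and 725 in library 2 on the log2(CPM + 1) scale, and the median difference in either direction was 1.37-fold. The exact binomial test called 8600 of all 23930 targets, 3876 higher in library 1 and 4724 in library 2. Over 14280 targets read at least 20 times, the chi-square statistic was 77.7 per degree of freedom, so the libraries were counted as 2 samples and not as 1 library deposited again.

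**Figure D3:**
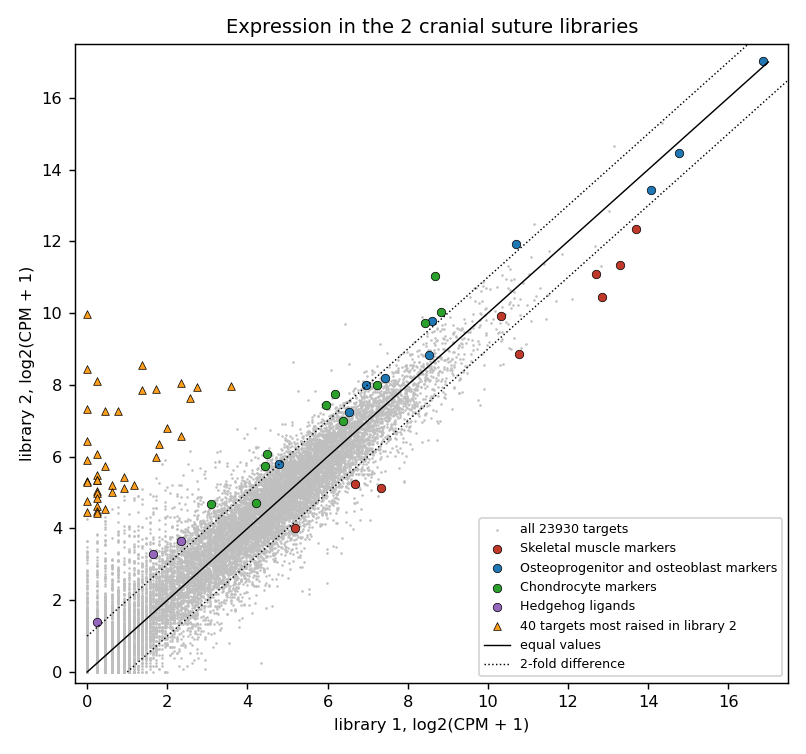
Each point is an amplicon target, with log2(CPM + 1) in library 1 on the x axis and in library 2 on the y axis; the solid line marks equal values and the dotted lines a 2-fold difference. All 9 skeletal muscle markers lie below the solid line, all 12 chondrocyte markers above it (11 are drawn in colour), and the 40 targets most raised in library 2 lie above the upper dotted line.

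All 9 skeletal muscle markers were higher in library 1 in the exact binomial test, with the same count adjusted over the list alone, and their median difference was 1.59 on the log2 scale, above all matched random lists. These 9 genes took 4.06% of the reads of library 1 and 1.29% of library 2. Acta1 was at 10110 and 2583 CPM and Myh8 at 6588 and 2188 CPM in library 1 and library 2. Among 18 further muscle genes, a list written after the values of the fixed list were seen, 16 were higher in library 1 in the same test and none in library 2. Neb was at 121 and 63.8 CPM, and Ryr1, which was not called, at 193 and 194 CPM. Neutrophil markers were higher in library 1 in 8 of 10 cases, with Ngp at 433 and 122 CPM, and Ltf was the reverse at 99.4 and 235 CPM. Tendon markers were higher in library 1 in 5 of 6 cases, with Tnmd at 362 and 86.6 CPM. The 10 genes most raised in library 1 included Chrna1, the acetylcholine receptor subunit of muscle, Mrln, Sh3bgr and Cox7a1. It also included Ttr, a thyroid hormone carrier made by liver and choroid plexus, at 62.7 and 4.62 CPM. The other 5 were Kcne1l, LOC102631912, Prr32, Ermap and Ube2e3.

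All 12 chondrocyte markers were higher in library 2 in the exact binomial test, also adjusted over the list alone, with a median difference of -1.30 on the log2 scale, below all matched random lists. Col2a1, the main cartilage collagen, was at 407 CPM in library 1 and 2078 CPM in library 2. Of 10 neuron markers 7 were higher in library 2 and 3 were not called, and 8 were higher when adjusted over the list alone. Tubb3 was at 67.1 and 338 CPM. Of 6 Schwann cell markers 5 were higher in library 2, with the same count adjusted over the list alone, and Sox10, a transcription factor of Schwann cells, was at 10.9 CPM in library 1 and 44.7 CPM in library 2. Of 7 meningeal markers 5 were higher in library 2, and none was higher in library 1. The 10 genes most raised in library 2 were Lcn11, Bpifb5, Bpifb6, BC051076, Bpifb4, Wfdc18, Scgb1c1, Cyp2a5, Obp2a and Vmo1. Several of these are known as secreted or metabolic genes of nasal and olfactory mucosa. Lcn11 had 0 reads in library 1 and 1001 CPM in library 2, at least 1889-fold higher against the limit of 3 reads. Obp2a, an odorant-binding protein gene, was at least 163-fold higher by the same measure. Cyp2a5 was at 1.59 and 230.0 CPM. The noncoding RNAs Rpph1, Rmrp and Malat1 were also higher in library 2. Rpph1 and Rmrp together took 2.98% of the reads of library 1 and 6.60% of library 2. Of 45 lists, 16 had a median difference outside the central 95% of matched random lists, 9 toward library 1 and 7 toward library 2.

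**Figure D4:**
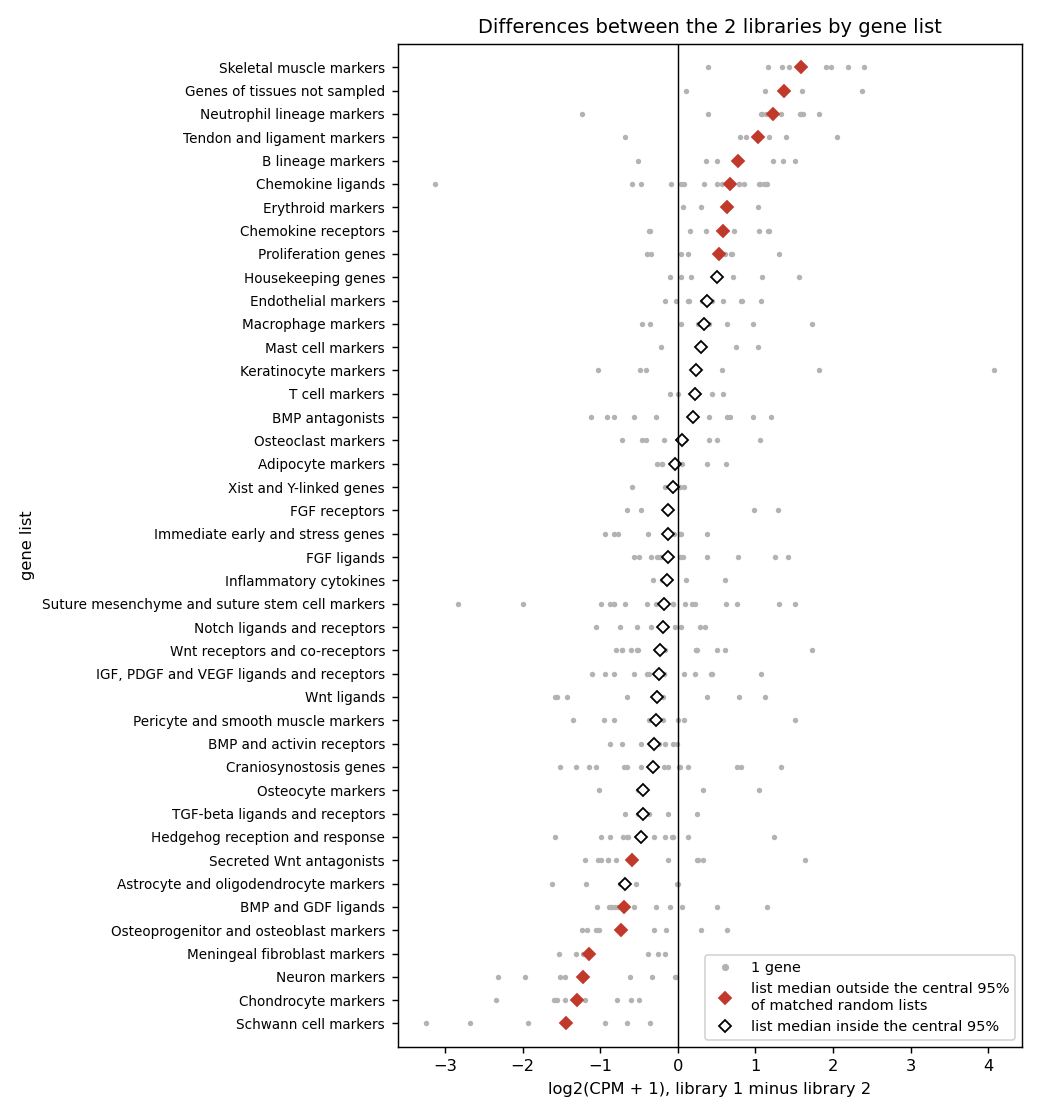
Difference in log2(CPM + 1), library 1 minus library 2, for the members at a mean of 1 CPM or more (grey points) and the median (diamonds) of those of the 45 fixed gene lists with at least 4 such members; filled diamonds lie outside the central 95% of 10000 matched random lists. Among these lists, skeletal muscle markers stand highest in library 1 (median 1.59) and Schwann cell markers highest in library 2 (median -1.44).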

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

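No paired analysis was possible because the series has 1 group. Counts of detected genes over all targets stayed within 1.5 times of their main values under every alternative run, from 11978 genes at 2 CPM to 14779 at 1 CPM in either library, and were 14142 without replicate 1 and 13794 without replicate 2. Within lists, detected chemokine ligands changed from 17 to 11 at 2 CPM and inflammatory cytokines from 4 to 7 in either library. The correlation of the libraries was 0.959 with a pseudocount of 5 CPM and 0.908 over genes at a mean of 1 CPM or more. The log2 ratio of Ihh to Shh, 2.17 with a pseudocount of 1 CPM, was 2.62 with 0.5 CPM, 1.06 with 5 CPM and 3.66 with none, because Shh lies near the pseudocount, and it stayed above 0 in each. With the pseudocount of 1 CPM it ranged from 2.10 to 2.24 when either library was left out. Without a pseudocount the ratios of the libraries were further apart, at 22.9 in library 1 and 6.96 in library 2. The ratio in library 1 rests on 1 Shh read. The rank of Cxcl12 among chemokine ligands ranged from 1 without library 1 to 3 without library 2, and its log2 ratio to Pf4 changed sign with them, from 0.06 to -1.04. The log2 ratio to Ccl9 did so too, from 0.56 to -0.19. The number of lists at or above the 95th percentile of level fell from 23 to 11 when only genes at a mean of 1 CPM or more were used. This removes the silent genes from the random lists, and also removes members below that mean from the lists themselves. The 1393 genes differing 2-fold became 2636 (1056 higher in library 1 and 1580 in library 2) at a mean of 1 CPM or more. They became 452 (259 and 193) at 50 CPM or more. The exact binomial test on recovered reads called 6351 (2961 and 3390) at 10 CPM or more. Thinning library 2 to the reads of library 1 gave 1413 differing genes and again 16 lists outside the central 95% of matched lists. Over the 45 lists and 5 alternatives, 8 list differences moved into the central 95% and 2 moved out of it. With members at a mean of 10 CPM or more, 5 lists that lay inside the central 95% changed sign: BMP antagonists (0.19 to -0.43), keratinocyte markers (0.24 to -0.41), FGF ligands (-0.13 to 0.07), adipocyte markers (-0.03 to 0.38) and sex-linked genes (-0.07 to 0.03). The lists that moved in were chemokine receptors, secreted Wnt antagonists, erythroid, B lineage and proliferation genes, and the list that moved out was glial markers. Low depth limits Shh and Pthlh, each with 1 read in library 1.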

Other observations

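The tests of unequal depth on olfactory neuron genes, of counting error on Ihh and of intronless against multi-exon families were chosen only after the result was seen. The gene lists of other tissues were written after the first tables had been seen, though before the values of their own members had been looked up. A total of 9 explanations for 4 patterns was tested, and 7 explanations for 3 patterns are weighed below. The pattern left out is the higher level of skeletal muscle genes in library 1, which was replaced by the pattern of intronless genes after its tests had been seen. Its 2 tests gave a median difference of 1.60 for the fixed muscle list after thinning and of 0.91 for muscle genes outside that list.

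Genes of tissues that lie outside the sampled sutures were present at clear levels. Of 12 olfactory sensory neuron genes, 10 were higher in library 2 in the exact binomial test and none in library 1, with a median difference of -2.62 on the log2 scale. Cnga2, the olfactory cyclic nucleotide channel, was at 1.24 and 27.0 CPM in library 1 and library 2, Gnal, the olfactory G protein, at 9.01 and 70.5 CPM, and Omp, the olfactory marker protein, at 11.1 and 247 CPM. Of 8 motile cilia genes, 6 were higher in library 2 and 1 in library 1, with Foxj1 at 3.71 and 29.2 CPM. Enamel genes of the tooth germ were also read in both libraries, with Amelx at 91.3 and 380 CPM and Ambn at 17.3 and 111 CPM, and all 6 tooth germ genes were higher in library 2 in the same test. Cortical neuron genes differed by a median of -0.29, inside the central 95% of matched random lists. Lung and lens genes had medians of 0.18 and 0.12 on the log2(CPM + 1) scale.

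Choroid plexus genes had a median difference of 0.14 and did not move together with Ttr, since Folr1 was at 4.94 and 1.08 CPM while Clic6 was at 3.36 and 22.7 CPM. The liver genes Alb and Apoa2 were at 5.83 and 0.316 CPM and at 5.47 and 1.14 CPM. Of 6 further liver genes none reached 1 CPM in both libraries, and 2 were higher in library 1 in the exact binomial test and none in library 2. Y-linked genes were read in both libraries, with Kdm5d at 7.42 and 8.42 CPM, beside at most 2 reads of Xist.

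The 40 genes most raised in library 2 had a median difference of -5.08 on the log2 scale and took 0.00509% of the reads of library 1 and 0.510% of library 2. Unequal depth is argued against as the whole cause, since the exact binomial test, which allows for the reads of each library, called 10 of 12 olfactory sensory neuron genes higher in library 2. Over all 23930 targets it called 4724 higher in library 2. More genomic DNA in library 2 than in library 1 is argued against as the cause. The share of intronless control genes (Vmn1r, Tas2r, Ifna and Krtap) with at least 3 reads fell by 12.0 percentage points (28.9% to 16.9%) from library 1 to the thinned library 2. That of olfactory receptor genes was 28.1% and 28.7%. This covers intronless genes only and does not exclude genomic DNA in both libraries, which is weighed below. A candidate explanation is that olfactory mucosa was among the material of library 2, and the olfactory sensory neuron list gave a median of -2.67 after thinning. Olfactory receptor genes with at least 3 reads numbered 297 in library 1 and 303 in the thinned library 2 of 1057. These counts are nearly equal and the second comes from a single random thinning, so they do not decide for or against this explanation. The receptor genes averaged 0.325 CPM per target in library 1 and 0.350 CPM in library 2. Whether olfactory material came with the dissection or from another library was not tested, and with 1 group no biological explanation was tested.

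Intronless receptor and keratin-associated genes, which suture tissue is not known to use, were read in both libraries. At least 3 reads were found for 27.9% of 226 genes with 1 coding exon in library 1 and 50.9% in the deeper library 2 (16.8% after thinning to the reads of library 1), against 1.34% and 6.04% (2.68% after thinning) of 149 genes of families with several coding exons (Vmn2r, Prl, Psg and Defb), where Psg genes made up 5 of the 9 read in library 2. Without thinning, the larger of the libraries' ratios of these shares was 0.119 (largest p of the exact Fisher tests 1.59e-13). Genomic DNA in both RNA samples would give such a ratio, as a hypothesis. For reads shared between near-identical family members, the share of Vmn2r genes with at least 3 reads was at most 0.109 of that of Vmn1r genes in either library. This does not decide the question, since Vmn2r genes without a source of reads would have none to share. The means of 0.330 and 0.237 CPM per intronless target lie under the 1 CPM detection level.

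The Hedgehog ligands were each higher in library 2, with differences of -1.17 for Shh, -1.30 for Ihh and -1.66 for Dhh on the log2(CPM + 1) scale. That scale understates changes near 1 CPM. As ratios of CPM, library 2 was 9.29-fold higher for Shh (1 read in library 1), 2.82-fold for Ihh and 4.18-fold for Dhh. Counting error of the reads is argued against for Ihh, with p = 1.77e-07 in the exact binomial test of its reads. With 23 Ihh reads in library 1 and no molecular identifiers, error from few starting molecules was not tested. A candidate explanation is a larger share of ligand-producing tissue, since cartilage genes outside the fixed list differed by a median of -1.22 and the fixed Schwann cell list by -1.44. All 6 tooth germ genes (median -1.53) and 10 of 12 olfactory sensory neuron genes (list median -2.62) were also higher in library 2. Which tissue gave the ligand reads, those of Shh included, was therefore not settled. With 2 libraries a shared origin and a coincidence cannot be told apart. A change in Hedgehog signalling within suture cells was not tested.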
